A study of Mus musculus with 16 samples.

How the data were processed

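RNA was sequenced from 8 populations of myeloid cells from wild-type C57BL/6 mouse bone marrow (femurs and tibias). Per the labels, marrow of 20 mice was pooled and sorted, and the whole procedure was repeated with another 20 mice, which gave 2 libraries per population and 16 in all. GMPs were sorted as Lin− c-Kit+ CD34+ FcγR-high Ly6C− Flt3− CD115-low cells and MDPs as Lin− c-Kit+ CD34+ FcγR-low Flt3+ CD115-high cells. GPs had the GMP gate but for Ly6C+, and the MP+cMoP fraction had the GP gate but for CD115-high. GMPs and MDPs were cultured with M-CSF at 50 ng/ml, cells were harvested on days 2, 3 and 4, and their lysates were pooled. MPs (from GMPs) and cMoPs (from MDPs) were c-Kit+ CD11b− Ly6C+ CD115-high, and G-mono and M-mono were c-Kit− CD11b+ Ly6G− CD115+ Ly6C-high F4/80−. Libraries were made with a KAPA kit and sequenced as 75 bp single-end reads over 4 lanes to 32.9 ± 1.7 M reads, per the labels. GP and MP+cMoP libraries were registered apart from the others, and lanes and dates per library are not given in the sources used here, so in comparisons with them a batch cannot be told apart from the population.

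The deposited values are counts of reads per Ensembl gene, 1 column per library, without normalization. Per the submitters' notes STAR 2.5.1b, Picard, featureCounts and limma were used on the mm10 build (GRCm38), with no role or order given. Annotation release, strand use and duplicate handling are not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart. Near-identical copies, such as Ly6c1 and Ly6c2, Hba-a1, class II, Ifit and immunoglobulin genes, Prss34 and Mcpt8, Chil3 and the Ear genes, carry uncertain counts too. Their reads can match more than 1 gene. Symbols were found for 42462 of 43346 gene identifiers, and 0.516 to 0.99% of counts fell on unnamed identifiers. Total counts were 24546190 to 31232949 per library, and 0.272 to 1.66% of them lay on 8 genes like ribosomal RNA.

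From these counts, edgeR 4.0.16 in R 4.3.3 tested 16311 genes that passed its expression filter. TMM factors were 0.903 to 1.09 and the biological coefficient of variation was 9.26%. One quasi-likelihood fit with robust spread held a coefficient for each of the 8 populations over all 16 libraries, and 13 contrasts were tested two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 2 contrasts by route subtract the change on the MDP route from that on the GMP route. The SE of a log2 fold change was derived from the F statistic. Gene lists, 20 of them with sort gate genes as a separate check, were tested with limma 3.58.1's camera with a preset correlation of 0.01. Distances and principal components used log2 CPM with a prior count of 2. A fold against a population with no count is a bound from a floor of 3 counts over the group, and with 1 to 3 counts a count ratio with a 95% interval is given; both cover counting error only.

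Comparisons, lists and the rule for naming genes were fixed before the data were examined. The rule names the 5 genes highest and lowest in each of the comparisons of GMPs with MDPs, MPs with cMoPs, G-mono with M-mono and MP+cMoP with GPs, and 3 in the others. They had to be called, to reach a mean of 10 CPM in the higher population and to have no overlap between libraries. It also names members with the smallest p of lists that passed, and the gate genes. Some genes that the rule names are not reported here. Which libraries are independent follows from the labels. Numbers follow the whole procedure, so a number marks a shared batch, and deviations of the 2 sets were correlated between populations: 6 of 28 pairs exceeded 0.1, from −0.028 to 0.378. The fit had no term for the set, and 1 alternative blocked it.

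On simulated counts for the real genes with 200 changed genes, 100 at 2-fold and 100 at 4-fold, the recovery was 72 and 97% for GMPs against MDPs, 70 and 92% for MPs against cMoPs, 76 and 92% for G-mono against M-mono and 77 and 85% for MP+cMoP against GPs. For the second step by route it was 56 and 82%. False calls were 3.35 to 9.29% of calls in 13 contrasts. Unequal replicate noise was not assessed, so the true rate can differ. Alternatives were RLE and upper quartile scaling, no expression filter, at least 5 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, only the compared populations, the replicate block and leaving out each library. For lists they were an estimated correlation, fry and the block, and for distances a prior count of 0.5 and the 500 most variable genes. Where fry is used, its p tests whether a list moves one way on balance, without comparing it with other genes. Other alternatives were chosen after seeing the data: the GMP and MDP pairs each summed, the block with a GC and length correction, and the second cMoP and M-mono libraries left out. No library was left out of the results otherwise.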

Results

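Gene expression was measured by RNA sequencing in 8 populations of mouse myeloid cells, each with 2 libraries, to ask whether granulocyte-monocyte progenitors (GMPs) and monocyte-dendritic cell progenitors (MDPs) make monocytes by separate routes. Both progenitors were sorted from bone marrow, and both were also cultured with M-CSF, the growth factor of the monocyte lineage. From the GMP cultures came monocyte progenitors (MPs) and Ly6C-high monocytes (G-mono), and from the MDP cultures came the common monocyte progenitors (cMoPs) and Ly6C-high monocytes (M-mono). Bone marrow also gave the granulocyte progenitors (GPs) and a mixed fraction of MPs and cMoPs (MP+cMoP), both sorted without culture. Levels are given as mean CPM (counts scaled to library size) ± SD with n = 2 libraries per population unless stated, and log2 fold changes ± SE with the adjusted p of edgeR's quasi-likelihood test. Beside each gene list stand the genes called higher or lower of those tested, the number called when p was adjusted over the list alone, and camera's adjusted p with its preset and, where that passed, an estimated correlation. No replicate pair was alike within counting noise over all genes, and by the median squared difference GMPs and MDPs came closest, at 1.43 and 1.23 times what counting alone gives, and cMoPs and M-mono lay farthest, at 14.1 and 10.05 times.

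In root mean square difference of log2 CPM over the 16311 tested genes, GMPs and MDPs lay 1.13 apart, MPs and cMoPs 0.816, and G-mono and M-mono 0.741. The SD over the 4 pairs of libraries behind each distance was 0.00178, 0.0534 and 0.0368. Libraries of one population were 0.275 to 0.468 apart. The mixed MP+cMoP fraction lay 0.831 from GPs, 0.839 from MDPs, 0.846 from cMoPs and 0.948 from MPs. The first principal component held 48.6% of the variance and set the cultured monocytes, at scores of 110.1 to 126.8, apart from the GMPs at −97.9 and −97.7. On the second component, with 19% of the variance, MPs lay at 71.5 and 79.2 and cMoPs at 12.5 and 11.2.

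**Figure D1:**
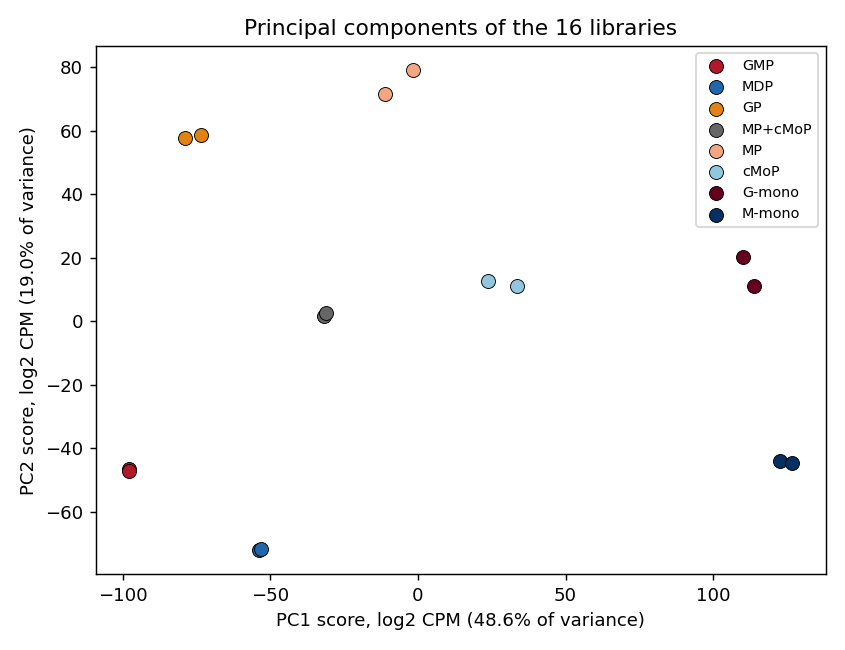
Scores of the 16 libraries on the first (48.6% of the variance, horizontal axis) and second (19% of the variance, vertical axis) principal components of log2 CPM, 1 point per library and 1 colour per population. The G-mono and M-mono libraries lie at 110.1 to 126.8 on the horizontal axis, and the MP libraries lie at 71.5 and 79.2 on the vertical axis, above the cMoP libraries at 12.5 and 11.2.

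Several genes recur below and lie at these positions of the mouse assembly GRCm38, each annotated as protein coding. Elane (ENSMUSG00000020125), which encodes neutrophil elastase, lies on chromosome 10 from 79886247 to 79888215. Ms4a3 (ENSMUSG00000024681), a membrane protein of granulocyte-monocyte progenitors, lies on chromosome 19 from 11629496 to 11640851. S100a8 (ENSMUSG00000056054), a calcium-binding subunit of calprotectin, lies on chromosome 3 from 90668978 to 90670035. Irf8 (ENSMUSG00000041515), a transcription factor of monocytes and dendritic cells, lies on chromosome 8 from 120736358 to 120756694, and F13a1 (ENSMUSG00000039109), coagulation factor XIII subunit A, lies on chromosome 13 from 36867178 to 37050244. Cd74 (ENSMUSG00000024610), the invariant chain of MHC class II, lies on chromosome 18 from 60803848 to 60812652. Siglech (ENSMUSG00000051504), a lectin of plasmacytoid dendritic cells, lies on chromosome 7 from 55768178 to 55778925, and Prg2 (ENSMUSG00000027073), the eosinophil major basic protein, lies on chromosome 2 from 84980461 to 84983632.

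The comparison of GMPs with MDPs asks how the parent cells of the 2 routes differ before culture. Values are given for GMPs first. Neutrophil granule genes were higher in GMPs. Elane stood at 1786 ± 28.6 against 123 ± 0.641 CPM, log2 fold change 3.86 ± 0.10, adjusted p = 2.48e-11. Ms4a3 stood at 429 ± 2.03 against 14.9 ± 0.312 CPM, log2 fold change 4.85 ± 0.10, adjusted p = 5.11e-12. Monocyte genes were higher in MDPs. Irf8 stood at 45.4 ± 1.15 against 1268 ± 7.47 CPM, log2 fold change −4.80 ± 0.09, adjusted p = 3.27e-12. F13a1 stood at 38.8 ± 1.12 against 1380 ± 14.2 CPM, log2 fold change −5.15 ± 0.11, adjusted p = 5.11e-12. The highest fold changes in GMPs belonged to genes of basophils, eosinophils and mast cells. Prg2 stood at 6653 ± 15.9 against 1.37 ± 0.103 CPM, log2 fold change 12.24 ± 1.25, adjusted p = 1.41e-05. The eosinophil peroxidase Epx stood at 3024 ± 48.5 against 0.419 ± 0.225 CPM, log2 fold change 12.79 ± 1.42, adjusted p = 2.68e-05. The basophil protease Prss34 stood at 3189 ± 44.7 against 0.275 ± 0.0207 CPM, log2 fold change 13.48 ± 1.26, adjusted p = 6.7e-06. Cd200r3, a receptor of basophils and mast cells, had 68.4 ± 0.882 CPM in GMPs and no count in MDPs, at least 1245-fold higher against a floor of 3 counts over the MDP libraries. Fcer1a, the IgE receptor alpha chain, had 1 count in MDPs and a count ratio of 4718 (95% interval 846 to 186400). Of the lowest in GMPs, the cytokine receptor Flt3 stood at 12.8 ± 1.45 against 530.1 ± 5.84 CPM, log2 fold change −5.37 ± 0.15, adjusted p = 2.69e-11. The receptor phosphatase Ptpro stood at 0.321 ± 0.155 against 23.1 ± 1.22 CPM, log2 fold change −6.14 ± 0.27, adjusted p = 2.05e-09. The liprin Ppfia4 (2.5 ± 0.298 against 104 ± 2.25 CPM) and the ephrin receptor Epha2 (0.61 ± 0.214 against 24.7 ± 0.209 CPM) had log2 fold changes of −5.37 ± 0.17 and −5.32 ± 0.59. Mycl, a transcription factor of the Myc family, had 3 counts in GMPs and a count ratio of MDPs to GMPs of 468 (95% interval 159.9 to 2273).

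Gene lists were read in the same comparison. Primary granule proteins were higher in GMPs (11 of 11 higher, 11 over the list alone, camera adjusted p = 4.68e-25, 0.0085 with an estimated correlation). Granulocyte regulators went the same way (8 of 11 higher and 1 lower, 10 over the list alone, camera adjusted p = 1.17e-11, 0.0362 with an estimated correlation). The transcription factor Gfi1 stood at 125 ± 3.39 against 19.5 ± 0.552 CPM. Eosinophil, basophil and mast cell markers were higher in GMPs (12 of 13 higher, 12 over the list alone, camera adjusted p = 4.04e-16, adjusted p = 0.0625 with an estimated correlation). The protease Mcpt8 stood at 1494 ± 0.702 against 8.38 ± 0.548 CPM. Erythroid and megakaryocyte markers were higher too (10 of 13 higher, 11 over the list alone, camera adjusted p = 9.81e-09, adjusted p = 0.107 with an estimated correlation). The platelet integrin Itga2b stood at 554 ± 1.69 against 14.7 ± 0.809 CPM. Macrophage genes were higher (12 of 15 higher and 2 lower, 14 over the list alone, camera adjusted p = 1.17e-11, adjusted p = 0.0692 with an estimated correlation). The lipid carrier Apoe stood at 259 ± 1.95 against 13.6 ± 0.543 CPM. Stem and multipotent progenitor genes were higher on balance (9 of 15 higher and 3 lower, 12 over the list alone, camera adjusted p = 0.00371, adjusted p = 0.294 with an estimated correlation). The transcription factor Gata2 stood at 619.5 ± 8.59 against 18.6 ± 0.424 CPM. Inflammatory cytokines were higher (6 of 14 higher and 1 lower, 7 over the list alone, camera adjusted p = 0.0178, adjusted p = 0.366 with an estimated correlation). Immediate early genes were higher on balance (8 of 16 higher and 2 lower, 10 over the list alone, camera adjusted p = 0.0351, adjusted p = 0.531 with an estimated correlation). Monocyte regulators and receptors were higher in MDPs (12 of 15 lower and 1 higher, 14 over the list alone, camera adjusted p = 7.95e-35, 6.88e-05 with an estimated correlation). Conventional dendritic cell markers were higher in MDPs (11 of 15 lower and 1 higher, 13 over the list alone, camera adjusted p = 7.42e-12, 0.00957 with an estimated correlation). The lectin Clec9a stood at 0.687 ± 0.176 against 26.8 ± 0.793 CPM. Plasmacytoid dendritic cell markers were too (6 of 10 lower and 2 higher, 9 over the list alone, camera adjusted p = 0.000856, adjusted p = 0.159 with an estimated correlation). MHC class II genes were higher in MDPs (7 of 10 lower and 1 higher, 8 over the list alone, camera adjusted p = 0.011, adjusted p = 0.294 with an estimated correlation). Mitosis genes were higher in MDPs (16 of 16 lower, 16 over the list alone, camera adjusted p = 5.95e-05, adjusted p = 0.258 with an estimated correlation). DNA replication genes were too (10 of 16 lower and 1 higher, 11 over the list alone, camera adjusted p = 0.0243, adjusted p = 0.531 with an estimated correlation).

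Pattern recognition receptors went both ways between GMPs and MDPs (7 of 15 lower and 6 higher, 14 over the list alone, camera adjusted p = 0.00981, adjusted p = 0.098 with an estimated correlation). Their median log2 fold change of 0.25 differed in sign from their mean of −0.26 and from the test, which called them lower in GMPs. Median, mean and test did not share a sign in 28 of 260 list results, of which 1, this one, passed. The other lists did not pass. Secondary and tertiary granule proteins were higher on balance (4 of 14 higher and 1 lower, 5 over the list alone, camera adjusted p = 0.175). Interferon response genes were mostly not called (3 of 15 lower and 1 higher, 4 over the list alone, camera adjusted p = 0.688). Cholesterol synthesis genes leaned higher (6 of 17 higher, 6 over the list alone, camera adjusted p = 0.112). Glycolysis genes leaned higher (6 of 14 higher, 6 over the list alone, camera adjusted p = 0.106). B and T lymphoid markers leaned higher (8 of 15 higher and 2 lower, 10 over the list alone, camera adjusted p = 0.462). Sort gate genes went both ways (5 of 11 higher and 4 lower, 9 over the list alone, camera adjusted p = 0.3). Read as a check of the labels, Csf1r, the M-CSF receptor CD115, was higher in MDPs (55.9 ± 1.19 against 502 ± 4.22 CPM), as was Flt3, and the Fc receptor Fcgr3 was higher in GMPs (193 ± 1.04 against 5.42 ± 0.000685 CPM), as the gates were set. Kit stood at 429 ± 5.79 against 268 ± 3.9 CPM, log2 fold change 0.68 ± 0.17, adjusted p = 0.00556. Cd34 stood at 337 ± 2.53 against 803 ± 7.13 CPM, log2 fold change −1.25 ± 0.28, adjusted p = 0.00283. Both calls ended when each pair of GMP and MDP libraries was summed to 1, a setting chosen after seeing the data, in case p was too low. In all, 6773 of 16311 genes were called, 3717 higher and 3056 lower in GMPs (1898 higher and 876 lower by at least 2-fold). With 1 library left out, log2 values were Epx at 13.48 without MDP 1, Ptpro at −6.74 without GMP 2.

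MPs against cMoPs asks whether the difference between the parents was still there among the monocyte progenitors that grew from them. Neutrophil genes were higher in MPs. S100a9, the partner of S100a8 in calprotectin, stood at 1584 ± 32.7 against 10 ± 6.53 CPM, log2 fold change 7.30 ± 0.78, adjusted p = 4.85e-05. S100a8 stood at 1352 ± 3.87 against 23.7 ± 15.4 CPM, log2 fold change 5.83 ± 0.57, adjusted p = 1.72e-05. Ltf, which encodes lactoferrin, stood at 121 ± 92.8 against 0.273 ± 0.168 CPM, log2 fold change 8.77 ± 1.49, adjusted p = 0.00122. Camp, the cathelicidin, stood at 19 ± 10.8 against 0.175 ± 0.0847 CPM, log2 fold change 6.73 ± 1.22, adjusted p = 0.0019. Itgb2l, an integrin chain, had 13.9 ± 6.92 CPM in MPs and no count in cMoPs, at least 237-fold higher. The chitinase-like Chil1 had 3 counts in cMoPs and a count ratio of 385 (95% interval 131 to 1870). Genes of antigen presentation were higher in cMoPs. The class II chain H2-Aa stood at 0.225 ± 0.0471 against 65.6 ± 29.1 CPM, log2 fold change −8.16 ± 0.65, adjusted p = 1.36e-06. The class II chain H2-Eb1 stood at 0.188 ± 0.0581 against 28.3 ± 11.9 CPM, log2 fold change −7.20 ± 0.71, adjusted p = 8.72e-06. Cd74 stood at 1.24 ± 0.298 against 149.7 ± 72.8 CPM, log2 fold change −6.91 ± 0.54, adjusted p = 1.16e-06. Ciita, the transactivator of these genes, had 1 count in MPs and 16.3 ± 7.11 CPM in cMoPs, a count ratio of 869 (95% interval 156 to 34380). Siglech had no count in MPs and 10 ± 0.303 CPM in cMoPs, at least 179-fold higher. Of the cMoP pair, the second library was the higher in Cd74, by 1.03 on the log2 scale, and in H2-Aa, by 0.94.

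Of the lists, those of granulocytes were higher in MPs and those of monocytes and dendritic cells in cMoPs. Primary granule proteins were higher in MPs (10 of 11 higher, 10 over the list alone, camera adjusted p = 3.0e-20, 0.00877 with an estimated correlation). The serine protease Prss57 stood at 171 ± 5.9 against 31.1 ± 3.72 CPM. Secondary and tertiary granule proteins were higher (10 of 14 higher and 1 lower, 11 over the list alone, camera adjusted p = 2.82e-06, adjusted p = 0.308 with an estimated correlation). Against the rest, the collagenase Mmp8 stood at 21.9 ± 0.876 against 122 ± 22.3 CPM. Granulocyte regulators were higher (7 of 11 higher, 7 over the list alone, camera adjusted p = 4.86e-13, 0.0209 with an estimated correlation). The transcription factor Ets1 stood at 40.8 ± 0.131 against 1.61 ± 0.214 CPM. Eosinophil, basophil and mast cell markers were higher (6 of 13 higher, 7 over the list alone, camera adjusted p = 0.00882, adjusted p = 0.569 with an estimated correlation). Prg2 stood at 28.2 ± 34.2 against 0.579 ± 0.431 CPM. Much of this lay in library MP 1, with Prg2, Prss34 and Epx at 52.4, 26.7 and 23.2 CPM, against 4.05, 1.45 and 0.23 in MP 2. Monocyte regulators were higher in cMoPs (14 of 15 lower and 1 higher, 15 over the list alone, camera adjusted p = 2.14e-23, 0.000384 with an estimated correlation). The fractalkine receptor Cx3cr1 stood at 3.59 ± 0.913 against 72.1 ± 2.65 CPM. MHC class II genes were all higher in cMoPs (10 of 10 lower, 10 over the list alone, camera adjusted p = 3.77e-11, 0.0285 with an estimated correlation). Conventional dendritic cell markers were higher in cMoPs (11 of 15 lower, 13 over the list alone, camera adjusted p = 2.93e-19, 0.00342 with an estimated correlation). The integrin Itgax stood at 0.563 ± 0.015 against 20.9 ± 3.86 CPM. Plasmacytoid dendritic cell markers were higher in cMoPs (7 of 10 lower, 8 over the list alone, camera adjusted p = 2.89e-10, 0.0209 with an estimated correlation). Pattern recognition receptors were lower in MPs (7 of 15 lower and 1 higher, 8 over the list alone, camera adjusted p = 0.00241, adjusted p = 0.0633 with an estimated correlation). The inflammasome sensor Nlrp3 stood at 40.4 ± 2.16 against 95.2 ± 1.84 CPM. Immediate early genes were lower in MPs (7 of 16 lower, 7 over the list alone, camera adjusted p = 0.00202, adjusted p = 0.509 with an estimated correlation).

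Between MPs and cMoPs, 4678 of 16311 genes were called, 2284 higher and 2394 lower in MPs (742 higher and 825 lower by at least 2-fold). Of 11 gate genes 5 were higher and 3 lower in MPs. Csf1r stood at 209.5 ± 6.13 against 444 ± 12.4 CPM, log2 fold change −1.08 ± 0.06, adjusted p = 1.19e-07. Itgam, which encodes CD11b, stood at 525 ± 3.6 against 191 ± 27.4 CPM, Kit at 272 ± 30.3 against 110 ± 39.4 CPM, Fcgr3 at 324 ± 2.65 against 246 ± 41.8 CPM, Flt3 at 0.989 ± 0.425 against 25.2 ± 0.401 CPM and Cd34 at 61.2 ± 8.14 against 267 ± 72 CPM (edgeR adjusted p of at most 0.00521). The call of Fcgr3 ended with only the compared libraries (adjusted p = 0.141). Ly6c2, whose reads the counting could have split with its near copy Ly6c1, was not called, at 1364 ± 32.8 against 1220 ± 387 CPM, log2 fold change 0.16 ± 0.20, adjusted p = 0.58. The count of calls was 2731 without MP 1, 3037 without MP 2, 7366 without cMoP 1, 2979 without cMoP 2 and 1971 with only the 4 compared libraries. Leaving out 1 library also gave Ltf at 9.40 and Prg2 at 2.80 (not called) without MP 1. Without MP 2 Ltf was at 7.64, Camp at 5.99 and Prg2 at 6.49. Without cMoP 1 Ltf was at 9.58 and Prg2 at 4.999 (not called). Without cMoP 2 Ltf was at 8.25, Camp at 6.31 and Prg2 at 6.67 (none called), S100a9 at 8.20, Cd74 at −6.30 and S100a8 at 6.72. Under limma-voom the calls of Ltf, Camp and Prg2 ended, at adjusted p = 0.102, 0.0729 and 0.153. Without the second cMoP and M-mono libraries, a setting chosen after seeing the data, the edgeR calls of Itgb2l, Ltf, Camp and Prg2 ended.

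The monocytes at the end of each route were compared to see what difference remained between G-mono and M-mono. Neutrophil genes were higher in G-mono. Ltf, Camp and Itgb2l were higher in the second G-mono and MP library, S100a8 only in G-mono. Which cells of these bulk libraries held them was not tested. Ltf stood at 148 ± 129 against 2.44 ± 1.87 CPM, log2 fold change 5.91 ± 1.11, adjusted p = 0.00276. S100a8 stood at 725 ± 287 against 21.7 ± 14.9 CPM, log2 fold change 5.06 ± 0.55, adjusted p = 5.88e-05. Elane stood at 477 ± 25.8 against 93.2 ± 5.47 CPM, log2 fold change 2.36 ± 0.10, adjusted p = 1.1e-08. Ms4a3 stood at 56.1 ± 5.79 against 6.33 ± 1.08 CPM, log2 fold change 3.15 ± 0.11, adjusted p = 2.57e-09. Arginase 1 (Arg1) stood at 72.8 ± 38.7 against 0.185 ± 0.0302 CPM, log2 fold change 8.59 ± 0.48, adjusted p = 1.2e-07. Chil1 (12.5 ± 9.85 against 0.225 ± 0.26 CPM) and the steroid dehydrogenase Akr1c18 (10.5 ± 2.65 against 0.205 ± 0.115 CPM) had log2 fold changes of 5.75 ± 0.85 and 5.64 ± 0.54. Cldn11, a tight junction protein, had 10.6 ± 2.62 CPM in G-mono and no count in M-mono, at least 170.3-fold higher. Genes of dendritic cells were higher in M-mono. Siglech had 2 counts in G-mono and 29 ± 2.2 CPM in M-mono, a count ratio of 768 (95% interval 212 to 6351). The surface protein Cd7 had 1 count in G-mono and a count ratio of 620.4 (95% interval 111 to 24550). The lectin Cd209a stood at 0.114 ± 0.0132 against 13.6 ± 0.144 CPM, log2 fold change −6.85 ± 0.28, adjusted p = 3.3e-08. The prostaglandin dehydrogenase Hpgd stood at 0.5 ± 0.165 against 83.1 ± 15.2 CPM, log2 fold change −7.39 ± 0.30, adjusted p = 1.1e-08. The adhesion receptor Adgre4 stood at 0.222 ± 0.081 against 34 ± 27.8 CPM, log2 fold change −7.21 ± 0.69, adjusted p = 1.09e-05.

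Granule and dendritic cell lists separated the monocytes as they did the progenitors. Primary granule proteins were all higher in G-mono (11 of 11 higher, 11 over the list alone, camera adjusted p = 4.88e-46, 0.00119 with an estimated correlation). Secondary and tertiary granule proteins were higher (12 of 14 higher, 13 over the list alone, camera adjusted p = 4.26e-09, adjusted p = 0.129 with an estimated correlation). Granulocyte regulators were higher on balance (5 of 11 higher and 1 lower, 6 over the list alone, camera adjusted p = 6.56e-08, adjusted p = 0.0686 with an estimated correlation). Gfi1 stood at 17.2 ± 0.794 against 2.26 ± 0.276 CPM. Conventional dendritic cell markers were higher in M-mono (9 of 15 lower, 9 over the list alone, camera adjusted p = 1.46e-30, 0.000629 with an estimated correlation). The peptidase Dpp4 stood at 0.435 ± 0.0238 against 21.6 ± 1.05 CPM. Plasmacytoid dendritic cell markers were higher in M-mono (9 of 10 lower, 9 over the list alone, camera adjusted p = 3.29e-22, 0.00353 with an estimated correlation). MHC class II genes were higher in M-mono (9 of 10 lower, 9 over the list alone, camera adjusted p = 1.54e-08, adjusted p = 0.0544 with an estimated correlation). Of the M-mono pair, the second library was the higher in Cd74, by 0.66 on the log2 scale, and in H2-Aa, by 0.85. Monocyte regulators were lower in G-mono on balance (8 of 15 lower and 3 higher, 11 over the list alone, camera adjusted p = 0.000226, 0.0483 with an estimated correlation). Cx3cr1 stood at 32.2 ± 8.7 against 416 ± 31.4 CPM. Interferon response genes were lower in G-mono (14 of 15 lower, 14 over the list alone, camera adjusted p = 8.4e-10, adjusted p = 0.163 with an estimated correlation). Ifit2, whose family shares sequence, stood at 11.5 ± 3.01 against 79.9 ± 49 CPM. Pattern recognition receptors were lower in G-mono (8 of 15 lower and 1 higher, 10 over the list alone, camera adjusted p = 3.46e-07, 0.00636 with an estimated correlation). Tlr2 stood at 80.7 ± 6.05 against 214 ± 3.62 CPM. DNA replication genes were higher in G-mono (12 of 16 higher, 14 over the list alone, camera adjusted p = 6.48e-05, adjusted p = 0.275 with an estimated correlation). Glycolysis genes were higher in G-mono (10 of 14 higher, 14 over the list alone, camera adjusted p = 4.57e-06, adjusted p = 0.157 with an estimated correlation). The glucose transporter Slc2a1 stood at 171 ± 3.05 against 111 ± 0.518 CPM. Mitosis genes did not pass (2 of 16 higher, 0 over the list alone, camera adjusted p = 0.0544, adjusted p = 0.0437 with the replicate block).

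Between the monocytes, 3886 of 16311 genes were called, 1759 higher and 2127 lower in G-mono (445 higher and 841 lower by at least 2-fold). The gate genes Itgam (1396 ± 24.3 against 1204 ± 53.5 CPM, log2 fold change 0.21 ± 0.11, adjusted p = 0.209), Adgre1 (256 ± 19.5 against 284 ± 0.149 CPM, log2 fold change −0.15 ± 0.11, adjusted p = 0.358) and Ly6c2 (869 ± 97.6 against 735 ± 238 CPM, log2 fold change 0.24 ± 0.20, adjusted p = 0.439) were not called, while Csf1r was lower in G-mono (935 ± 25.1 against 1819 ± 82.1 CPM, log2 fold change −0.96 ± 0.06, adjusted p = 3.96e-07). Ly6c2 stood at a log2 fold change of −0.074 without M-mono 1 and was called without M-mono 2, at 0.62. The count of calls was 2478 without G-mono 1 and 1637 with only the 4 compared libraries. Other values that leaving out 1 library moved were Arg1 at 7.89, Ltf at 6.60, Chil1 at 6.39 and Ciita at −4.78 without G-mono 1, Ltf at 4.52, Chil1 at 4.59 and Spib at −6.73 without G-mono 2, Ltf at 5.27, Chil1 at 4.89, Adgre4 at −7.88 and S100a8 at 4.47 without M-mono 1, Ltf at 7.04, Chil1 at 8.08, Akr1c18 at 6.36, Adgre4 at −5.96, S100a8 at 6.03 and Ifit2 at −1.97 without M-mono 2. Without the second cMoP and M-mono libraries the call of Ltf ended.

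**Figure D2:**
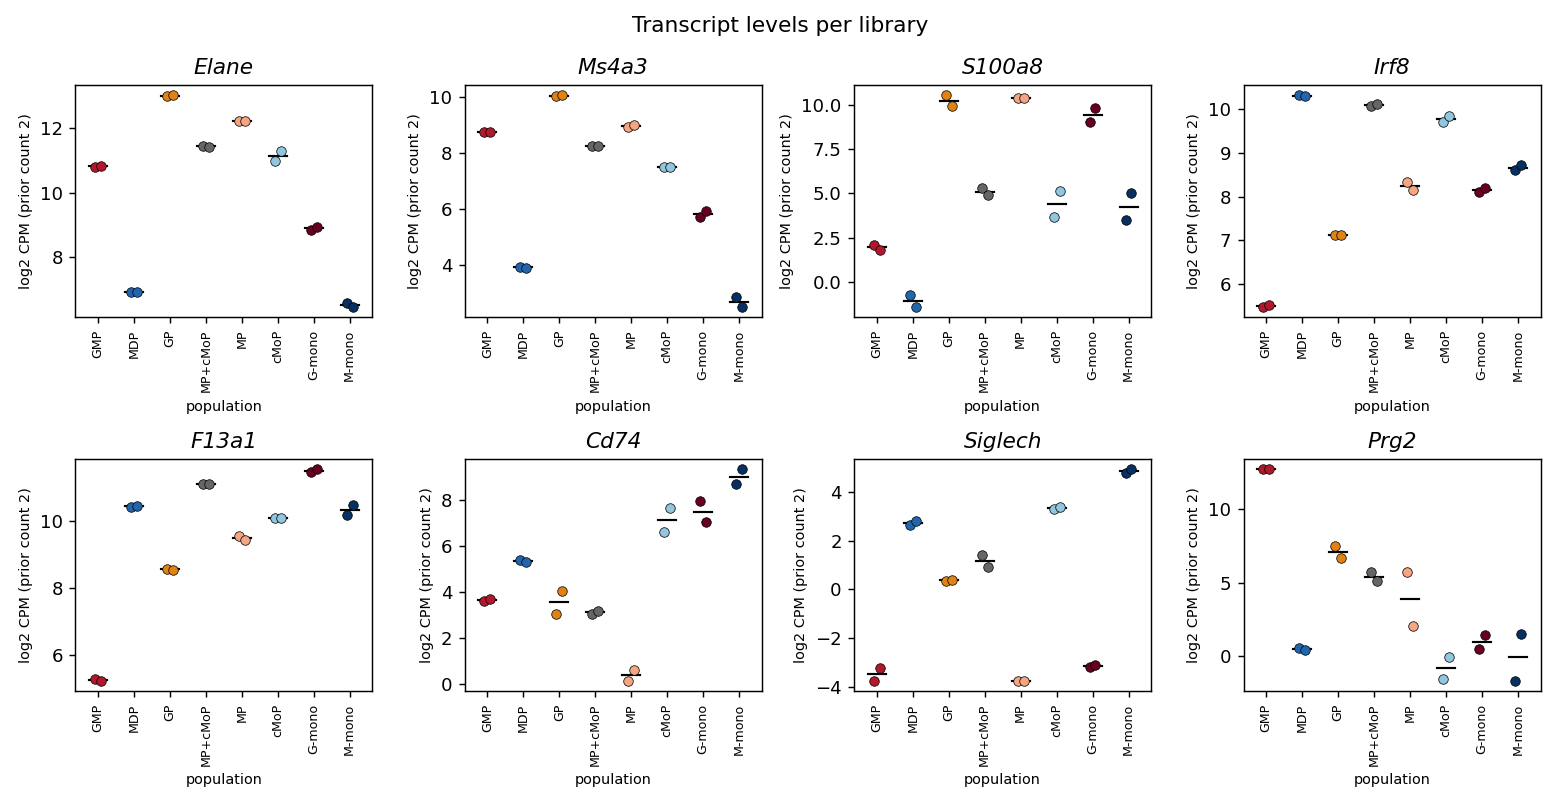
Level of 8 genes in each library, as log2 CPM with a prior count of 2 (vertical axes), in the 8 populations (horizontal axes), with points for libraries and a line at the mean. Elane, Ms4a3 and S100a8 are higher in MP than in cMoP and Cd74 and Siglech are higher in cMoP, the same direction as between G-mono and M-mono, and the mean of Prg2 in GMP is 6653 CPM.

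The differences between the routes were then compared stage by stage, in pairs of comparisons that share no library. Of the genes higher in GMPs than MDPs, 1233 were also higher in MPs than cMoPs, where independent lists would share 520.5, and of those lower, 1115 were also lower, where 448.5 would be shared. Opposite calls numbered 455 against 973.5. From the progenitor to the monocyte stage, MPs against cMoPs and G-mono against M-mono shared 721 genes higher on the GMP side (246.3 for independent lists) and 953 lower (312.2), with 256 opposite (556). GMPs against MDPs and G-mono against M-mono shared 697 higher (400.8) and 848 lower (398.5), with 722 opposite (814.3). At 2-fold or more 168 were opposite there, more than the 121.8 of independent lists. Fisher's exact test gave adjusted p of at most 1.57e-63 for these 6 shared lists, though genes are not independent replicates. Libraries of a set share a procedure, and deviations between the sets correlated between cMoPs and M-mono (r = 0.378), so comparisons can also share noise. Ms4a3 and Siglech were among the genes that kept their direction at each stage, with Ms4a3 at 4.85, 1.48 and 3.15 on the log2 scale.

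In the uncultured marrow, the mixed MP+cMoP fraction was compared with GPs, which share its gate but for the level of CD115. Values are given for MP+cMoP first. Monocyte genes were higher in the mixed fraction. The transcription factor Klf4 stood at 198 ± 21.2 against 10 ± 0.98 CPM, log2 fold change 4.30 ± 0.14, adjusted p = 2.91e-10. Irf8 stood at 1093 ± 23.4 against 138 ± 0.128 CPM, log2 fold change 2.98 ± 0.08, adjusted p = 5.59e-11. Fibronectin (Fn1) stood at 174 ± 7.6 against 3.9 ± 0.843 CPM, log2 fold change 5.48 ± 0.27, adjusted p = 7.55e-09. The myeloid receptor Trem2 stood at 19.6 ± 0.668 against 0.723 ± 0.0274 CPM, log2 fold change 4.75 ± 0.32, adjusted p = 1.61e-07. The calcium-binding S100a4 (20.8 ± 4.33 against 0.765 ± 0.19 CPM) and the scaffold protein Ahnak (180.1 ± 41.9 against 8.21 ± 1.11 CPM) had log2 fold changes of 4.76 ± 0.43 and 4.46 ± 0.21. By fold, GPs led most in these genes. The thyrotropin receptor Tshr stood at 0.232 ± 0.0212 against 16.7 ± 2.82 CPM, log2 fold change −6.14 ± 0.32, adjusted p = 4.09e-08. S100a9 stood at 30.3 ± 12.1 against 1105 ± 512 CPM, log2 fold change −5.19 ± 0.70, adjusted p = 0.000165. The septin Sept5 (0.873 ± 0.263 against 41.1 ± 10.4 CPM), the acyltransferase Mogat2 (1.18 ± 0.232 against 52.1 ± 6.68 CPM) and Wfdc21 (1.52 ± 0.254 against 59.2 ± 7.91 CPM) had log2 fold changes of −5.55 ± 0.52, −5.46 ± 0.40 and −5.28 ± 0.43. Ms4a3 stood at 308 ± 0.441 against 1062 ± 12.8 CPM and the gate gene Csf1r at 553 ± 11.5 against 90 ± 0.933 CPM, with edgeR adjusted p of at most 9.16e-09.

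Primary granule proteins were all lower in MP+cMoP (11 of 11 lower, 11 over the list alone, camera adjusted p = 1.86e-23, 0.00988 with an estimated correlation). Secondary and tertiary granule proteins were lower (12 of 14 lower and 1 higher, 14 over the list alone, camera adjusted p = 0.00239, adjusted p = 0.671 with an estimated correlation). Granulocyte regulators were lower (9 of 11 lower and 1 higher, 11 over the list alone, camera adjusted p = 1.21e-13, 0.022 with an estimated correlation). Gfi1 stood at 39.1 ± 1.06 against 325 ± 2.17 CPM. Monocyte regulators were higher in MP+cMoP (14 of 15 higher, 14 over the list alone, camera adjusted p = 5.9e-45, 2.65e-05 with an estimated correlation). Ms4a6c stood at 392 ± 17.9 against 51.4 ± 0.623 CPM. Conventional dendritic cell markers were higher on balance (8 of 15 higher and 1 lower, 10 over the list alone, camera adjusted p = 1.58e-06, 0.0381 with an estimated correlation). The lectin Clec10a stood at 14.8 ± 0.383 against 2.17 ± 0.352 CPM. MHC class II genes were higher (5 of 10 higher, 5 over the list alone, camera adjusted p = 0.0371, adjusted p = 0.625 with an estimated correlation). Pattern recognition receptors were higher on balance (7 of 15 higher and 3 lower, 12 over the list alone, camera adjusted p = 1.46e-05, 0.0203 with an estimated correlation). The DNA sensor Tlr9 stood at 22.2 ± 2.03 against 1.54 ± 0.294 CPM. Macrophage genes did not pass (5 of 15 higher and 1 lower, 6 over the list alone, camera adjusted p = 0.104). The adhesion molecule Vcam1 stood at 13.6 ± 2.87 against 273 ± 30 CPM. In this comparison 5094 of 16311 genes were called, 2641 higher and 2453 lower (1052 higher and 955 lower by at least 2-fold).

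The mixed fraction was also placed between the cultured progenitors, over the 1567 genes that differed at least 2-fold between MPs and cMoPs. In 901 of them its mean log2 CPM lay between the cultured populations, in 453 at or beyond the cMoP value and in 213 at or beyond the MP value. It lay nearer to cMoPs in 985 of the 1567, with a median position of 0.31 where 0 is cMoP and 1 is MP.

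From GMPs to MPs, the first step of the GMP route, 3 genes rose the most, with MPs given first. The chitinase-like Chil3 stood at 1370 ± 3.02 against 0.942 ± 0.911 CPM, log2 fold change 10.52 ± 0.86, adjusted p = 1.99e-06. S100a9 stood at 1584 ± 32.7 against 1.49 ± 0.0427 CPM, log2 fold change 10.05 ± 0.92, adjusted p = 5.08e-06. The neutrophilic granule protein Ngp stood at 1116 ± 30.1 against 1.49 ± 0.381 CPM, log2 fold change 9.55 ± 1.05, adjusted p = 2.14e-05. The lymphocyte GTPase Gimap1, the lipoxygenase Alox12e and the cation channel Trpc6 had 17.6 ± 0.49, 16.8 ± 0.345 and 12.1 ± 0.302 CPM in GMPs. They had no count in MPs and were at least 312-, 298- and 214-fold lower. Erythroid and megakaryocyte markers fell (12 of 13 lower and 1 higher, 13 over the list alone, camera adjusted p = 3.11e-25, 0.00431 with an estimated correlation). Itga2b stood at 2.92 ± 2.12 against 554 ± 1.69 CPM. Eosinophil, basophil and mast cell markers fell (12 of 13 lower, 12 over the list alone, camera adjusted p = 1.29e-10, adjusted p = 0.0565 with an estimated correlation). B and T lymphoid markers fell (13 of 15 lower, 13 over the list alone, camera adjusted p = 2.73e-06, 0.00431 with an estimated correlation). Stem cell genes fell (13 of 15 lower, 13 over the list alone, camera adjusted p = 4.45e-13, 0.0168 with an estimated correlation). Cholesterol synthesis genes all rose (17 of 17 higher, 17 over the list alone, camera adjusted p = 1.79e-20, 0.000449 with an estimated correlation). MPs were cultured and GMPs were not, so culture cannot be told apart from this step. Monocyte regulators rose (10 of 15 higher and 3 lower, 13 over the list alone, camera adjusted p = 3.91e-15, 0.000889 with an estimated correlation). Pattern recognition receptors rose (11 of 15 higher, 11 over the list alone, camera adjusted p = 1.73e-07, 0.00431 with an estimated correlation). Here 7998 genes were called, 3829 higher and 4169 lower in MPs. Log2 values were, for Chil3, 12.15 without GMP 1 and 9.75 without GMP 2, and, for Itga2b, −8.61 without MP 1 and −6.97 without MP 2.

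From MDPs to cMoPs, the first step of the other route, 3 genes again rose the most, with cMoPs given first. The myosin Myo18b stood at 40.8 ± 2 against 0.0919 ± 0.0277 CPM, log2 fold change 8.73 ± 0.23, adjusted p = 8.84e-11. Chil3 stood at 35 ± 23.6 against 0.146 ± 0.049 CPM, log2 fold change 7.86 ± 1.09, adjusted p = 0.000135. The ficolin Fcnb stood at 22.3 ± 13 against 0.11 ± 0.0539 CPM, log2 fold change 7.61 ± 0.74, adjusted p = 3.21e-06. Elane rose from 123 ± 0.641 to 2243 ± 339.9 CPM and Ms4a3 from 14.9 ± 0.312 to 179.7 ± 0.859. Carbonic anhydrase 1 (Car1) and the anion exchanger Slc4a1 had 22.2 ± 0.707 and 15.6 ± 0.222 CPM in MDPs and no count in cMoPs, at least 382- and 268-fold lower. Ermap, an erythroblast membrane protein, had 1 count in cMoPs and a count ratio of MDPs to cMoPs of 911 (95% interval 163 to 36000). Erythroid and megakaryocyte markers fell (12 of 13 lower, 12 over the list alone, camera adjusted p = 3.01e-14, adjusted p = 0.0526 with an estimated correlation). B and T lymphoid markers fell (14 of 15 lower, 14 over the list alone, camera adjusted p = 5.83e-05, 0.0221 with an estimated correlation). The DNA polymerase Dntt stood at 0.679 ± 0.0915 against 77.5 ± 0.279 CPM. Cholesterol synthesis genes all rose (17 of 17 higher, 17 over the list alone, camera adjusted p = 7.02e-34, 3.29e-05 with an estimated correlation). Primary granule proteins rose (10 of 11 higher, 10 over the list alone, camera adjusted p = 6.54e-15, 0.0221 with an estimated correlation). Pattern recognition receptors rose (11 of 15 higher and 2 lower, 13 over the list alone, camera adjusted p = 2.9e-06, 0.0221 with an estimated correlation). Monocyte regulators went both ways (8 of 15 higher and 7 lower, 15 over the list alone, camera adjusted p = 0.058, adjusted p = 0.0411 with the replicate block). Here 8959 genes were called, 4542 higher and 4417 lower in cMoPs. Leaving out cMoP 2 put Chil3 at 6.93 and Fcnb at 6.84 on the log2 scale. The 2 first steps shared 2529 rises, 2387 falls and 589 opposite calls, where independent lists would share 1066, 1129 and 2198. Both went from uncultured to cultured cells, so a shared effect of culture cannot be told apart.

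Whether the first step differed between the routes was tested as an interaction, the change from GMPs to MPs less the change from MDPs to cMoPs, which called 4190 genes, 1978 higher and 2212 lower. F13a1 went from 38.8 ± 1.12 to 715 ± 38.2 CPM on the GMP route and from 1380 ± 14.2 to 1087 ± 5.71 on the MDP route, an interaction of 4.55 ± 0.13 (adjusted p = 8.16e-10). Irf8 went from 45.4 ± 1.15 to 303 ± 24.8 CPM and from 1268 ± 7.48 to 874 ± 61.3 CPM (3.27 ± 0.11, adjusted p = 3.06e-09). Elane rose on both routes, from 1786 ± 28.6 to 4749 ± 0.708 and from 123 ± 0.641 to 2243 ± 340 CPM (−2.78 ± 0.13, adjusted p = 2.17e-08). The progesterone receptor Pgr reached 145 ± 5.17 CPM in MPs from 0.259 ± 0.132 in GMPs, against 3.53 ± 0.336 in cMoPs and 1.01 ± 0.356 in MDPs. Cd74 fell from 12.5 ± 0.767 to 1.24 ± 0.298 CPM on the GMP route and stood at 40.6 ± 2.29 in MDPs and 149.7 ± 72.8 in cMoPs. The count was 2772 without MDP 2, 6609 without cMoP 1 and 1942 with the GMP and MDP pairs each summed, and leaving out 1 library put Pgr at 7.93 without GMP 1 and Cd74 at −4.60 without cMoP 2.

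From MPs to G-mono, the second step of the GMP route, the chemokine Ccl7 and the receptor Slamf7 appeared. They had 39.2 ± 27.5 and 24.5 ± 0.114 CPM in G-mono and no count in MPs, at least 725- and 436-fold higher. The syndecan Sdc4 had 1 count in MPs and a count ratio of 2289 (95% interval 411 to 90470). Myeloperoxidase (Mpo) stood at 773 ± 98.6 against 16910 ± 389 CPM, log2 fold change −4.45 ± 0.20, adjusted p = 2.04e-09. The cadherin Celsr1 stood at 3.59 ± 0.597 against 78.8 ± 4.78 CPM, log2 fold change −4.45 ± 0.19, adjusted p = 1.18e-09. The actin-binding Shroom2 stood at 0.142 ± 0.143 against 10.7 ± 1.84 CPM, log2 fold change −6.11 ± 0.50, adjusted p = 4.65e-07. Primary granule proteins all fell (11 of 11 lower, 11 over the list alone, camera adjusted p = 5.29e-31, 0.00242 with an estimated correlation). Macrophage genes rose (14 of 15 higher and 1 lower, 15 over the list alone, camera adjusted p = 9.45e-22, 0.0263 with an estimated correlation). The endosomal protein Cd68 stood at 438 ± 29.1 against 40.7 ± 0.765 CPM. Pattern recognition receptors all rose (15 of 15 higher, 15 over the list alone, camera adjusted p = 4.74e-16, 0.000715 with an estimated correlation). Monocyte regulators rose (12 of 15 higher and 1 lower, 13 over the list alone, camera adjusted p = 3.16e-16, 0.000715 with an estimated correlation). Inflammatory cytokines rose (11 of 14 higher, 11 over the list alone, camera adjusted p = 1.09e-06, adjusted p = 0.103 with an estimated correlation). The chemokine Ccl2 stood at 171 ± 92.7 against 0.171 ± 0.137 CPM. Glycolysis genes did not pass (9 of 14 higher and 1 lower, 10 over the list alone, camera adjusted p = 0.0511, adjusted p = 0.0388 with the replicate block). Of 7781 genes called, 51.4% were higher in G-mono, and 39.1% with upper quartile scaling, which moved the median log2 fold change by −0.124. Values on the log2 scale were Shroom2 at −7.88 and Ccl2 at 9.23 without G-mono 1, Shroom2 at −5.43 without G-mono 2, Ccl2 at 9.29 without MP 1, Ccl2 at 11.09 without MP 2. Ccl7 was at 58.6 CPM in G-mono 1 and 19.8 in G-mono 2, and its edgeR call ended with only the 4 compared libraries, at adjusted p = 0.161.

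From cMoPs to M-mono, the scavenger receptor Marco and the chemokine Cxcl2 had 11.5 ± 15.3 and 11.2 ± 0.739 CPM in M-mono and no count in cMoPs, at least 198- and 193-fold higher. The macrophage elastase Mmp12 had 1 count in cMoPs and a count ratio of 1467 (95% interval 263 to 57980). Mpo stood at 281 ± 104 against 11100 ± 378 CPM, log2 fold change −5.31 ± 0.21, adjusted p = 8.81e-10. The granule protein Nkg7 stood at 0.473 ± 0.148 against 19.1 ± 3.88 CPM, log2 fold change −5.33 ± 0.20, adjusted p = 7.07e-10. The mucin Muc13 stood at 1.99 ± 0.68 against 61.9 ± 5.25 CPM, log2 fold change −4.95 ± 0.16, adjusted p = 3.29e-10. Csf1r rose to 1819 ± 82.1 CPM. Primary granule proteins all fell (11 of 11 lower, 11 over the list alone, camera adjusted p = 2.51e-39, 0.00173 with an estimated correlation). Macrophage genes rose (14 of 15 higher and 1 lower, 15 over the list alone, camera adjusted p = 8.56e-23, 0.0135 with an estimated correlation). The transcription factor Maf stood at 253 ± 0.00303 against 1.86 ± 0.963 CPM. Pattern recognition receptors rose (14 of 15 higher, 14 over the list alone, camera adjusted p = 1.31e-18, 0.000234 with an estimated correlation). Monocyte regulators rose (12 of 15 higher and 3 lower, 15 over the list alone, camera adjusted p = 1.04e-05, 0.0138 with an estimated correlation). Interferon response genes all rose (15 of 15 higher, 15 over the list alone, camera adjusted p = 3.46e-09, adjusted p = 0.207 with an estimated correlation). Oasl2 stood at 81.4 ± 40.8 against 1.1 ± 0.397 CPM. Of 8570 genes called, 51.4% were higher in M-mono, and 40.2% with upper quartile scaling, which moved the median log2 fold change by −0.131. Marco was at 0.66 CPM in M-mono 1 and 22.3 in M-mono 2, and its call ended with only the compared libraries (edgeR adjusted p = 0.0543) and under limma-voom (adjusted p = 0.121). When 1 library was left out, log2 values were Oasl2 at 5.57 without M-mono 2, Maf at 7.74 without cMoP 2. The 2 second steps shared 3106 rises, 2588 falls and 172 opposite calls, where independent lists would share 1079, 966.7 and 2043.

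The second step differed between the routes in 2393 genes, 1133 higher and 1260 lower in the interaction of the change from MPs to G-mono with that from cMoPs to M-mono. F13a1 rose from 715 ± 38.2 to 2872 ± 116 CPM on the GMP route and stood at 1087 ± 5.71 in cMoPs and 1285 ± 187 in M-mono, an interaction of 1.76 ± 0.12 (adjusted p = 4.8e-06). Cd74 rose from 1.24 ± 0.298 to 189 ± 79.3 CPM and stood at 149.7 ± 72.8 and 527 ± 167 CPM on the other route (5.43 ± 0.65, adjusted p = 0.000174). The iron exporter Slc40a1 went from 66.7 ± 9.48 to 17.1 ± 2.21 CPM on the GMP route and from 2.41 ± 0.0873 to 33.1 ± 12.5 on the MDP route (−5.74 ± 0.38, adjusted p = 3.32e-06). Arg1 was at 72.8 ± 38.7 CPM in G-mono and at 0.056 ± 0.025, 0.116 ± 0.0533 and 0.185 ± 0.0302 in MPs, cMoPs and M-mono. The count was 678 with only the 8 compared libraries, fell with the GMP and MDP pairs each summed and moved both ways without single libraries. Cd74 stood at 4.82 without cMoP 2. Arg1 stood at 9.03 without it, where its call ended, and at 8.87 without G-mono 1.

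**Figure D3:**
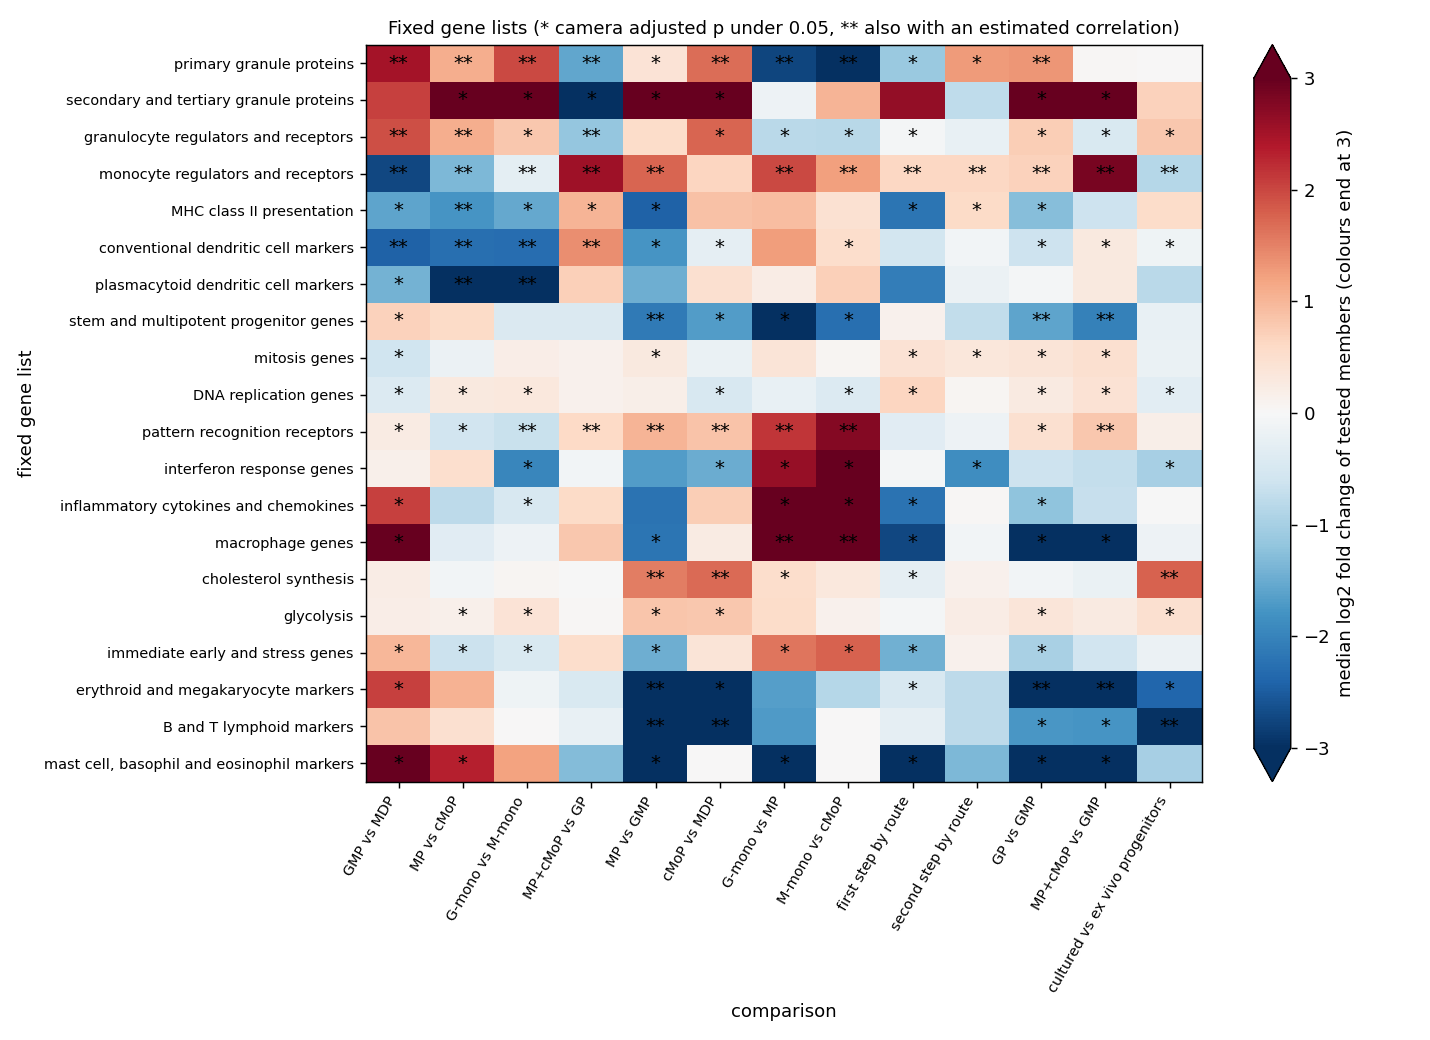
Median log2 fold change (colour, ending at 3) of the tested members of each of 20 fixed gene lists (vertical axis) in each of 13 comparisons (horizontal axis), with 1 star for camera adjusted p under 0.05 and 2 stars where the call also held with an estimated correlation. Primary granule proteins have 2 stars in the comparisons of GMP with MDP, MP with cMoP and G-mono with M-mono, and the direction of the test can differ from that of the median, as for pattern recognition receptors in GMP against MDP (0.25).

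GPs against GMPs, which differ in the gate by Ly6C, showed granule genes higher. S100a9 stood at 1105 ± 512 against 1.49 ± 0.0427 CPM, log2 fold change 9.53 ± 0.91, adjusted p = 9.04e-06. Camp stood at 226 ± 158 against 0.337 ± 0.178 CPM, log2 fold change 9.35 ± 0.98, adjusted p = 1.83e-05. Ltf stood at 119.5 ± 109 against 0.319 ± 0.251 CPM, log2 fold change 8.51 ± 1.42, adjusted p = 0.000632. The mast cell carboxypeptidase Cpa3 stood at 4.55 ± 0.759 against 819 ± 2.4 CPM, log2 fold change −7.49 ± 0.63, adjusted p = 2.57e-06. Prss34 stood at 19.1 ± 0.429 against 3189 ± 44.7 CPM, log2 fold change −7.39 ± 0.88, adjusted p = 4.98e-05. The guanylate cyclase subunit Gucy1a1 stood at 0.0958 ± 0.0305 against 16.5 ± 1.08 CPM, log2 fold change −7.37 ± 0.45, adjusted p = 2.99e-07. Primary granule proteins were all higher in GPs (11 of 11 higher, 11 over the list alone, camera adjusted p = 4.97e-18, 0.0373 with an estimated correlation). Erythroid and megakaryocyte markers were lower (12 of 13 lower, 12 over the list alone, camera adjusted p = 5.24e-17, 0.0438 with an estimated correlation). Stem cell genes were lower (11 of 15 lower, 11 over the list alone, camera adjusted p = 5.79e-13, 0.0438 with an estimated correlation). Eosinophil, basophil and mast cell markers were lower (12 of 13 lower, 12 over the list alone, camera adjusted p = 1.14e-08, adjusted p = 0.155 with an estimated correlation). In total 6592 of 16311 genes were called, 2802 higher and 3790 lower in GPs. Single libraries moved log2 values, to Camp at 10.03 and Ltf at 9.68 without GMP 2, Camp at 8.37 and Ltf at 7.02 without GP 1, Ltf at 7.90 without GMP 1, Ltf at 9.23 without GP 2. The call of Ltf ended under limma-voom (adjusted p = 0.0774) and, with edgeR, with only the 4 compared libraries (adjusted p = 0.085).

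MP+cMoP against GMPs, the same marrow gate but for Ly6C and CD115, showed monocyte genes higher. F13a1 stood at 2180 ± 11.8 against 38.8 ± 1.12 CPM, log2 fold change 5.81 ± 0.11, adjusted p = 6.35e-12. Irf8 stood at 1093 ± 23.4 against 45.4 ± 1.15 CPM, log2 fold change 4.59 ± 0.09, adjusted p = 6.35e-12. Klf4 stood at 198 ± 21.2 against 2.34 ± 0.178 CPM, log2 fold change 6.40 ± 0.17, adjusted p = 3.13e-11. Ptpro stood at 26.4 ± 4.48 against 0.321 ± 0.155 CPM, log2 fold change 6.33 ± 0.27, adjusted p = 1.51e-09. The membrane protein Tmem178 had 3 counts in GMPs and a count ratio of 210.4 (95% interval 71.7 to 1023). Fcer1a stood at 0.214 ± 0.0974 against 86.4 ± 0.869 CPM, log2 fold change −8.62 ± 0.44, adjusted p = 4.98e-08. The muscle LIM protein Csrp3 had 3 counts in MP+cMoP and a count ratio of GMPs to MP+cMoP of 504 (95% interval 172 to 2444), and the flippase Atp8b1 had 1 count and a ratio of 720.4 (95% interval 129 to 28490). Monocyte regulators were higher in MP+cMoP (13 of 15 higher and 1 lower, 14 over the list alone, camera adjusted p = 1.09e-44, 2.35e-05 with an estimated correlation). Pattern recognition receptors were higher (10 of 15 higher and 2 lower, 13 over the list alone, camera adjusted p = 1.57e-08, 0.00609 with an estimated correlation). Conventional dendritic cell markers were higher on balance (7 of 15 higher and 3 lower, 11 over the list alone, camera adjusted p = 0.0473, adjusted p = 0.327 with an estimated correlation, adjusted p = 0.0533 with the replicate block). Erythroid and megakaryocyte markers were lower (12 of 13 lower, 12 over the list alone, camera adjusted p = 4.32e-18, 0.0344 with an estimated correlation). Stem cell genes were lower (13 of 15 lower, 13 over the list alone, camera adjusted p = 2.34e-13, 0.0411 with an estimated correlation). In total 7237 of 16311 genes were called, 3271 higher and 3966 lower in MP+cMoP, and Ptpro stood at 6.93 without GMP 2.

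The cultured progenitors, MPs and cMoPs as 1 set of 4 libraries, were compared with the uncultured MP+cMoP fraction to show what differed between culture and marrow. The SD of the cultured side includes the difference between MPs and cMoPs. Thrombospondin 1 (Thbs1) stood at 2387 ± 1282 against 5.49 ± 0.0817 CPM, log2 fold change 8.59 ± 0.15, adjusted p = 3.2e-12. The progesterone receptor Pgr stood at 74.1 ± 81.5 against 0.09 ± 0.0774 CPM, log2 fold change 7.91 ± 0.62, adjusted p = 1.08e-06. Most of its cultured level lay in MPs, at 145 ± 5.17 CPM, against 3.53 ± 0.336 in cMoPs. The transglutaminase Tgm2 stood at 209 ± 225 against 0.679 ± 0.0118 CPM, log2 fold change 6.86 ± 0.36, adjusted p = 3.17e-08. The 3 genes lowest in culture follow. The kappa constant gene Igkc stood at 0.111 ± 0.197 against 89.4 ± 58.8 CPM, log2 fold change −10.29 ± 0.85, adjusted p = 5.61e-06. It was at 47.8 CPM in MP+cMoP 1 and 131 in MP+cMoP 2. The variable genes Igkv15-103 and Ighv7-1 had 1 and 2 counts in the 4 cultured libraries and count ratios of marrow to culture of 2327 (95% interval 417 to 91980) and 858 (95% interval 237 to 7096). Cholesterol synthesis genes were all higher in culture (17 of 17 higher, 17 over the list alone, camera adjusted p = 1.38e-61, 3.83e-06 with an estimated correlation). Glycolysis genes were higher (13 of 14 higher, 14 over the list alone, camera adjusted p = 2.13e-06, adjusted p = 0.188 with an estimated correlation). Monocyte regulators were lower on balance (9 of 15 lower and 3 higher, 13 over the list alone, camera adjusted p = 4.64e-10, 0.00329 with an estimated correlation). Ms4a6c stood at 151 ± 109.5 against 392 ± 17.9 CPM. B and T lymphoid markers were lower (14 of 15 lower, 14 over the list alone, camera adjusted p = 0.000154, 0.0379 with an estimated correlation). Interferon response genes were lower (8 of 15 lower and 1 higher, 9 over the list alone, camera adjusted p = 0.0326, adjusted p = 0.804 with an estimated correlation, adjusted p = 0.0517 with the replicate block). In total 6813 of 16311 genes were called, 3307 higher and 3506 lower in culture. Among log2 values with 1 library left out were Pgr at 7.24 without MP+cMoP 1, Pgr at 9.14 and Igkc at −9.39 without MP+cMoP 2, Igkc at −13.04 without MP 1, Igkc at −11.48 without cMoP 1.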

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

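These results come from tests of a difference between the routes that were planned, and their genes were named by a fixed rule that picks by fold or p. The first step, GMPs to MPs against MDPs to cMoPs, differed in 4190 genes by edgeR's interaction test, and values are log2 interactions ± SE, positive where the change on the GMP route was the higher. They were F13a1 4.55 ± 0.13, Irf8 3.27 ± 0.11, Nlrp3 2.28 ± 0.12, Mcm7, a replication helicase subunit, 0.64 ± 0.09, and among the highest Pgr 7.31 ± 0.91 and the antizyme inhibitor Azin2 5.20 ± 0.43. Negative ones were Ms4a3 −3.37 ± 0.13, Elane −2.78 ± 0.13, the granulocyte regulator Cebpe −7.59 ± 0.34, Cd74 −5.21 ± 0.68, Apoe −4.82 ± 0.27, the immediate early gene Egr1 −5.63 ± 0.33, the histidine decarboxylase Hdc −4.72 ± 0.19 and Gata2 −6.91 ± 0.41. Lowest were the kinase Dmpk −9.77 ± 0.91, E-cadherin (Cdh1) −8.87 ± 0.31 and Cd200r3, whose fitted −14.46 is no bound since MDPs had no count. The edgeR adjusted p was at most 0.00031. Leaving out 1 library gave Cdh1 at −9.97 without MDP 1, Cdh1 at −8.26 without MDP 2, Gata2 at −7.68 without MP 1.

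Of the lists, monocyte regulators rose more on the GMP route (9 of 15 higher and 3 lower, 12 over the list alone, camera adjusted p = 6.55e-16, 0.00147 with an estimated correlation). DNA replication genes were higher in the interaction (14 of 16 higher and 1 lower, 15 over the list alone, camera adjusted p = 3.09e-05, adjusted p = 0.289 with an estimated correlation). On the MDP route 10 of these fell and 1 rose, and on the GMP route 6 rose and 1 fell. Mitosis genes were also higher (9 of 16 higher, 10 over the list alone, camera adjusted p = 0.00254, adjusted p = 0.459 with an estimated correlation). Primary granule proteins rose more on the MDP route (5 of 11 lower, 5 over the list alone, camera adjusted p = 2.33e-10, adjusted p = 0.0937 with an estimated correlation). The next lists were also lower in the interaction, and none of them passed with an estimated correlation (lowest adjusted p = 0.0937). By camera's adjusted p they were granulocyte regulators (0.00254), MHC class II genes (0.00254), inflammatory cytokines (0.00254), macrophage genes (1.56e-12), cholesterol synthesis genes (0.0028), immediate early genes (2.95e-07), erythroid and megakaryocyte markers (0.02) and eosinophil, basophil and mast cell markers (2.9e-09). Called genes lower numbered 5 of 11, 7 of 10, 5 of 14, 8 of 15, 6 of 17, 9 of 16, 4 of 13 and 4 of 13, and when adjusted over the list alone 6, 9, 6, 8, 6, 11, 4 and 5 were called in either direction.

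The second step, MPs to G-mono against cMoPs to M-mono, differed in 2393 genes by the same test. Higher were Arg1 9.58 ± 2.09, Ciita 5.64 ± 1.19, Cd74 5.43 ± 0.65, Ms4a6c 1.84 ± 0.09, F13a1 1.76 ± 0.12, Ms4a3 1.67 ± 0.13, the mitosis gene Birc5 0.63 ± 0.12 and Slamf7, whose fitted 9.29 is no bound since MPs had no count. Arg1 had 3 counts in MPs and Ciita 1, so their values depend on the fit as well. Adjusted p was at most 0.0333 by edgeR. Lower were Adgre4 −6.07 ± 1.72, Slc40a1 −5.74 ± 0.38, the RNA sensor Ddx58 −5.38 ± 0.31 and Ifit2 −3.83 ± 0.49. Leaving out 1 library gave Ciita at 4.77 (call lost) without MP 1, 7.97 without MP 2 and 4.65 without G-mono 1. Ifit2 was at −3.02 without M-mono 2. Adgre4 ranged from −4.83 to −6.75, its call lost without any 1 of the MP, cMoP and G-mono libraries. Calls also ended for Adgre4 under limma-voom (adjusted p = 0.152) and, by edgeR, for Adgre4 (0.165) and Arg1 (0.0596) without the filter, for Adgre4 (0.119), Ciita (0.065) and Birc5 (0.095) with only the compared populations, and for Adgre4 with the pairs summed (0.0581) and with the GC and length correction (0.0906), and for Arg1 without the second cMoP and M-mono libraries (0.425). Monocyte regulators were higher (8 of 15 higher, 10 over the list alone, camera adjusted p = 6.16e-14, 0.00248 with an estimated correlation). Primary granule proteins were higher (7 of 11 higher and 2 lower, 10 over the list alone, camera adjusted p = 1.17e-09, adjusted p = 0.139 with an estimated correlation). Mitosis genes were higher (7 of 16 higher, 8 over the list alone, camera adjusted p = 0.000255, adjusted p = 0.512 with an estimated correlation). MHC class II genes were higher (3 of 10 higher, 5 over the list alone, camera adjusted p = 0.0441, adjusted p = 0.605 with an estimated correlation, adjusted p = 0.0829 with the replicate block). Interferon response genes were lower (9 of 15 lower, 12 over the list alone, camera adjusted p = 1.17e-09, adjusted p = 0.493 with an estimated correlation). Each population has 2 libraries, so single libraries were not tested as standing apart.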

How the results depend on the processing

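Chosen after seeing the data were the settings with the GMP and MDP pairs summed, with the GC and length correction, and without the second cMoP and M-mono libraries. Of 291 named gene results, all 291 kept direction and call with RLE, upper quartile scaling, DESeq2 and the replicate block, 289 without the filter (2 lost the call), 285 with limma-voom (6 lost), 281 with only the compared populations (10 lost), 288 with the pairs summed (3 lost) and 290 with the block and the GC and length correction (1 lost). With at least 5 CPM in 2 libraries 289 kept both and 2 had no value. With 1 library left out, 1292 of 1310 kept both, 15 lost the call, 1 gained it and 2 reversed, both of Ly6c2, which was not called with all libraries. It ranged from −0.13 (without cMoP 1) to 0.53 (without cMoP 2) in MPs against cMoPs, and from −0.074 (without M-mono 1) to 0.62 (without M-mono 2, called) in G-mono against M-mono. A lone library left in a population is assumed to vary like the others. Without the second cMoP and M-mono libraries 146 of 154 kept both, 6 lost the call and Ly6c2 gained it in these 2 comparisons.

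Counts of called genes stayed within 1.5 times under both scalings, both filters, DESeq2, limma-voom and the block (0.766 to 1.26 times). With only the compared populations they were 10280 for GMPs against MDPs, 1971 for MPs against cMoPs, 1637 for G-mono against M-mono, 4558 for M-mono against cMoPs and 678 for the second step by route. With the pairs summed they were 3995 for GMPs against MDPs, 1942 for the first step by route and 1427 for the second. Without 1 library they were 2731 to 7366 for MPs against cMoPs, 2478 to 4425 for G-mono against M-mono, 2772 to 6609 for the first step, 1258 to 4530 for the second and 4149 to 8311 for cultured against uncultured progenitors. The counts without cMoP 1 were the highest in these comparisons that include it, and the cause was not tested.

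Of 260 list results, 160 kept their direction and side of the threshold with an estimated correlation and 100 lost their call. The lists that passed then numbered 4 for GMPs against MDPs, 6 for MPs against cMoPs, 5 each for G-mono against M-mono and MP+cMoP against GPs, 6 for MPs against GMPs, 4 each for cMoPs against MDPs, G-mono against MPs, M-mono against cMoPs, GPs against GMPs and MP+cMoP against GMPs, 1 for each step by route and 3 for cultured against uncultured progenitors. The replicate block kept direction and side of the threshold in 249, with calls gained for 5 and lost for 3 (MHC class II genes in the second step at adjusted p = 0.0829 and conventional dendritic cell markers in MP+cMoP against GMPs at 0.0533 by camera among them), and changed no call of a named gene. Fry kept 218, with 37 calls gained and 2 lost. Reversed, and past no threshold, were with fry macrophage genes in MPs against cMoPs (adjusted p = 0.996), lymphoid markers in M-mono against cMoPs (0.195) and plasmacytoid dendritic cell markers in GPs against GMPs (0.385), and with the block the last of these (0.939), secondary granule proteins in the second step (0.67) and MHC class II genes in cultured against uncultured progenitors (0.954).

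Distances depend on the measure. With a prior count of 0.5 they were 1.29 for GMPs to MDPs, 0.966 for MPs to cMoPs, 0.865 for G-mono to M-mono, 0.935 for GPs to MP+cMoP, 1.15 for MP+cMoP to MPs and 1.04 for MP+cMoP to cMoPs. Over the 500 most variable genes they were 3.56, 2.57, 2.07, 2.13, 3.03 and 2.69. The order of the first 3 was the same in each.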

Other observations

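The tests for one cell pool, for fresh against cultured cells, for a set effect common to all populations and for other cells in the GMP sort were chosen only after the results were seen. So were the genes named for the second libraries. The GMP and MDP pairs differed by less than the others by the median, at 1.43 and 1.23 times counting noise. By chi-square per degree of freedom over all genes MDPs were lowest, at 1.44, but GMPs, at 12.4, lay above MP+cMoP (9.57) and MPs (10.9). Fresh sorting as the reason stays open, since of the GP and MP+cMoP pairs, also fresh, the lower was at 2.14 by the median, above GMPs, and at 9.57 by chi-square, below them. If both libraries of a population came from one cell pool, rare immunoglobulin transcripts should differ by counting noise alone, and their chi-square per degree of freedom was at most 1.04 in GMPs and MDPs (p = 0.709 and 0.401, chi-square test across genes, which are not independent replicates), against 189.6 in GPs and 60.4 in MP+cMoP. One pool for each pair is thus a candidate explanation, which the labels, giving 2 sets of mice, do not state. The SD and SE of GMPs and MDPs would then cover technical variation only, which is why the pairs were also summed. All contrasts share the fit, so any p could be too low.

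The second cMoP and M-mono libraries deviated from the first together, with r = 0.381 across 16139 genes with known GC content and length (0.378 over all tested). Slc39a10, a zinc transporter, was lower in the second by −1.86 in cMoPs and −1.37 in M-mono on the log2 scale, and Mt1, a metallothionein, was higher by 1.53 and 1.28. GC content and gene length are argued against as the whole cause, since r was 0.291 after their trends were removed. A difference in maturation is argued against as the whole cause by correlations with the step from MPs to G-mono of 0.116 for cMoPs and 0.0325 for M-mono, although Cd34 was lower in both second libraries and Cd74 higher, as in that step. A set effect common to all populations stays open. Of the 6 pairs among cultured populations 5 correlated over 0.1, as did GPs with MP+cMoP, while the 8 pairs across these reached at most 0.0946, and GMPs and MDPs would show none if each came from one pool. Differences between the 2 sets of mice or cultures stay open too and were not tested.

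GMPs held transcripts of other lineages. Late erythroid cells are argued against as the whole source by Alas2, Slc4a1, Hba-a1 and Hbb-bs, of which the highest was at 20.6 CPM, beside Itga2b at 554 ± 1.69 CPM, and mature connective tissue mast cells by Cma1 and Tpsb2, of which the higher was at 3.45 CPM, beside Cpa3 at 819 ± 2.4 CPM. Of 26 markers of the mast cell, basophil and eosinophil list and the erythroid and megakaryocyte list, 22 were higher in GMPs than in MDPs. Progenitors of these lineages inside the GMP gate cannot be told apart from expression by GMPs themselves, since each library is a bulk of cells.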
